A study of Danio rerio with 3 samples.

How the data were processed

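The data are 2-colour Agilent microarrays of zebrafish embryos, 3 samples in all, at 5, 12 and 24 hpf. Per the labels, eggs were bathed between 0 and 2 hpf in cortisol at 13.8 µM, which is 5 mg/L, or in vehicle at 2 ml of ethanol per 1 L, and then kept at 28.5 °C. Total RNA (200 ng) was labelled with Cy3 for vehicle and Cy5 for cortisol on every array, with no dye swap. The experiments with an antagonist and a receptor messenger that the study's title names are not analysed here.

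The deposited scanner files hold median pixel intensity and local background intensity per spot and channel, from Agilent Feature Extraction, whose version is not given in the sources used here. Decimals of the green signals are those that a mean over 4 arrays gives in 99.8% of spots at 5 hpf and that a mean over 3 arrays gives in 99.3% at 12 hpf. At 24 hpf 99.5% are those of the pixel median of a single array. The rule for 4 arrays is wide, since 99.9% met it at 24 hpf too. At 5 hpf, however, 55.5% met the rule for 3 arrays and 27.4% that for a single array. At 12 hpf 74.2% met the rule for 4 arrays. Decimals of the red signals and of the backgrounds were not checked. The authors also deposited a normalized log10 ratio of red over green and processed intensity values, background-subtracted and dye-normalized by the scanner software, per the file headers. At 24 hpf the deposited log10 ratio equals the ratio of the processed signals within 0.02 on the log2 scale for 100% of spots with a value, and at 5 and 12 hpf for 43.2% and 46.4%. Averaging ratios and signals separately over arrays would give such gaps, but their cause was not tested. No flags for saturation or outliers were in the files, so no spot was removed for either.

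From the scanner signals, background was corrected per array and channel with limma's normexp (offset 50) and ratios were normalized within each array by loess, with 1417 control spots given weight 0 (limma 3.58.1, R 4.3.3). Because the values at 5 and 12 hpf are read as means over arrays, this within-array correction is approximate there. Fitted first on every spot, normexp placed the mean red background at -196 at 5 hpf and -106 at 12 hpf, although only 1% of spots had a red signal minus background under -3.30 and -5.00. A few spots with extreme local background, the lowest at -6592.5 and -21025, pulled this fit. Spots with a local background over 2 times the array's median were therefore left out, 12 at 5 hpf, 9 at 12 hpf and 0 at 24 hpf, which brought these means to -14.6 and -6.58. Both still lay below the 1% limits of -3.30 and -5.00, as did the mean of -9.40 at 24 hpf against -8.50. This repair was made after the first fit had been seen to fail, and the values without it are among the alternatives. The deposited log2 ratio (the authors' log10 ratio rescaled) is an alternative, printed beside the counts and for some of the named genes, so a named gene without it may differ there as well. The choice between the 2 ratios was not blind: the ratio from the scanner signals was the planned one, the deposited ratio was for a time taken as the main one after counts under several settings had been seen, and the planned ratio was then restored. Across genes it correlated with the ratio used here at 0.78, 0.46 and 0.52 at 5, 12 and 24 hpf.

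Spots of a probe were averaged, then the measured probes of a gene. A probe was measured in a channel where its signal exceeded the mean plus 2 SD of 153 negative control spots, which was met in both channels by 31457, 20049 and 18831 of 43603 probes. Genes were named through the RefSeq table of assembly GRCz12tu, used for names only. Of the probes, 25258 were named by accession, 2766 by symbol, 1682 by a synonym, and 13897 kept the name in the file. Genes measured in 1 channel only were given a lower bound of their fold, from channel values after loess and Aquantile normalization, against the lowest signal among probes measured in the dim channel or the probe's own.

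With 1 set of values per stage there is no test. Genes at least 2-fold higher or lower are counted by size alone, and the number of arrays limits the precision. The design, the gene lists, the naming rule and all alternatives except the added ones were fixed before the data were examined. The text names, per stage, the 12 genes with the largest positive and the 12 with the largest negative log2 ratio among genes with a proper symbol, measured in both channels, with the same sign in all probes and in the deposited ratio. It also names up to 4 members of each list with the largest absolute ratio, the top genes of 1 channel only, and 12 genes fixed in advance. Each of 22 lists, 586 of whose 629 symbols were on the array, is given as the median of its measured members with its percentile among 10000 random lists of the same size matched on mean signal in 20 bins. A list below percentile 2.5 or above 97.5 is said to stand apart, as a description of these arrays. Computations used Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1.

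The steps were tested on simulated data, with red signals drawn from the real vehicle signals and scaled to each array's red range. Planted ratios came out smaller: probes planted at 3-fold had a median of 2.08-fold at 5 hpf (32511 probes measured), 1.51-fold at 12 hpf (20938 probes) and 1.97-fold at 24 hpf (18589 probes). Probes planted at 2-fold came out at 1.60-fold, 1.46-fold and 1.47-fold. In these simulations 55 of 95 measured 3-fold probes passed 2-fold at 5 hpf, 22 of 74 at 12 hpf and 29 of 59 at 24 hpf, and 0 unchanged probes did, so folds were understated in these simulations and many planted genes were missed. The simulated noise was set smaller than the spread between probes of a gene in the data (pooled SD 0.21, 0.33 and 0.33). The 0 unchanged calls therefore give no rate of false calls in the data. Of 400 lists of 25 genes drawn at random, 7.75% stood apart at 5 hpf (19309 genes), 5.00% at 12 hpf (12766 genes) and 3.75% at 24 hpf (12319 genes), where 5% are due by chance. The alternatives were other background corrections and normalizations, filters on dim probes, the brightest probe per gene, the scanner software's processed signals, the deposited ratio, other fold thresholds and unmatched random lists.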

Results

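Gene expression was measured in zebrafish embryos whose eggs had been bathed in the steroid hormone cortisol, or in its ethanol vehicle, for the first 2 hours after fertilisation. Embryos were collected at 5, 12 and 24 hours post fertilisation (hpf). Each stage is represented by 1 set of values from 2-colour oligonucleotide arrays, with vehicle RNA in green (Cy3) and cortisol RNA in red (Cy5). Per the labels, 4 replicates were run at 5 hpf, 3 at 12 hpf and a single experiment at 24 hpf. By the decimals of the green signals, the values at 5 and 12 hpf are read as the authors' means over those arrays. No spread between embryo batches could be computed at any stage, and no test or p-value is given. A log2 ratio above 0 means a higher signal in cortisol-treated embryos.

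The red channel differed greatly in brightness between stages. The 95th percentile of signal minus local background was 7318 in red and 3710 in green at 5 hpf, 330 and 4350 at 12 hpf, and 290 and 1978 at 24 hpf. Both channels lay above the negative controls for 19309 genes at 5 hpf, 12766 at 12 hpf and 12319 at 24 hpf. Between different probes of a gene the pooled SD of the log2 ratio was 0.21, 0.33 and 0.33, and between replicate spots of the same probe it was 0.054, 0.54 and 0.24, over 27, 12 and 12 probes. In simulated arrays of the same brightness, planted 3-fold ratios came out at a median of 2.08-fold, 1.51-fold and 1.97-fold at the 3 stages. Of 18 genes chosen as markers of early embryos, all 18 had a lower vehicle signal at 24 than at 5 hpf, and 24 of 25 late markers had a higher one, as the stage labels require.

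**Figure D1:**
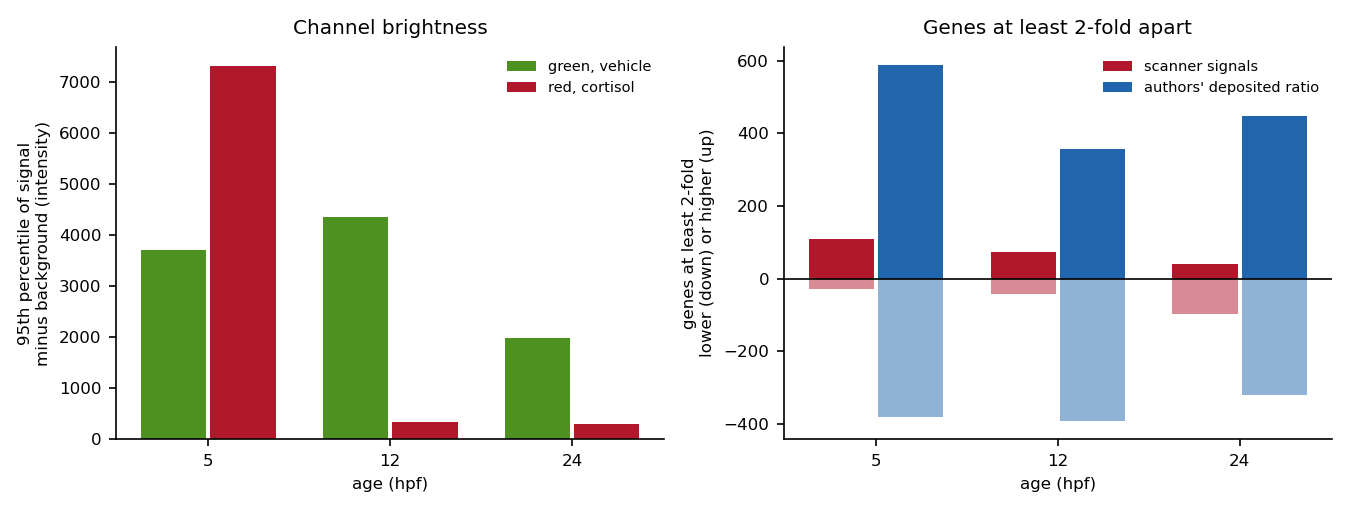
Left, the 95th percentile of signal minus background for the green vehicle channel and the red cortisol channel, by age in hours post fertilisation. Right, genes at least 2-fold higher (up, solid) or lower (down, pale) in cortisol-treated embryos, from the scanner signals and from the authors' deposited ratio. Red was 330 at 12 hpf and 290 at 24 hpf, and the deposited ratio gave more genes at every stage.

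The comparison at 5 hpf asked which transcripts differed shortly after the exposure, when the embryo's own genome has become active. Among heat shock genes, hsp70.2 had a log2 ratio of 1.62 and hsp70l of 1.2, both from dim green spots, and hsp70.3 of 0.80 with probes from 0.12 to 1.29, whereas the heat shock list as a whole had a median of 0.02, with 13 members higher and 11 lower. The oocyte transcript btg4 was higher by 1.59, the DNA methyltransferase gene dnmt3bb.1 by 2.06 and the link protein gene hapln4 by 2.93. A pair of genes from the glucocorticoid-responsive list was lower, the glutamine synthetase gene glula at -1.64 and ddit4 at -1.25. The epidermal keratin gene krt5 was lower as well, at -0.63.

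At 5 hpf, 110 genes were at least 2-fold higher and 27 at least 2-fold lower in cortisol-treated embryos. In the authors' deposited ratio these counts were 589 and 380, and the share of higher genes among them was 60.8% in place of 80.3%. Among 9444 genes with both channels over the median signal, averaged over such probes only, 56 were higher and 24 lower (70.0% higher) in the scanner signals and 46 and 67 (40.7% higher) in the deposited ratio. Of the genes 2-fold higher in the scanner signals, 91 of 110 were also 2-fold higher in the deposited ratio, as were 23 of 27 lower ones. The remaining genes in the upper 12 were f9b at 4.71, odf3l2a at 2.39, nck1a at 2.13, grid2ipb at 1.99, s100a10b at 1.68, rnd2 at 1.67, fat3a at 1.63 and micall2b at 1.60. Of these, f9b, grid2ipb and fat3a were well under 2-fold in the deposited ratio, at 0.43, 0.31 and 0.51, while nck1a and rnd2 were larger at 3.85 and 3.42. Of the 12 highest genes at 5 hpf, 5 had both channels over the median signal, and of the 12 lowest, 10 had. The other lower genes were slc22a7b.1 at -1.86, wdr48a at -1.63, zdhhc16a at -1.60, cbr4 at -1.45, iah1 at -1.40, dcxr at -1.20, fgg at -1.13, rnaset2 at -1.12, lgals1l1 at -1.10 and sf3b5 at -1.08. In the deposited ratio slc22a7b.1, wdr48a and fgg were smaller, at -0.55, -0.44 and -0.30, and zdhhc16a and lgals1l1 were larger at -4.15 and -2.72. Among list members, irf7 was higher by 1.2, mcl1b by 1.02 and nr1d2a by 1.01 (2.88 in the deposited ratio).

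Of 22 gene lists, 5 stood apart from random lists at 5 hpf, all toward lower values, where 1.1 would do so at the nominal 5%, although 7.75% of simulated random lists did at this stage. The median log2 ratio of 24 epidermis and ionocyte genes was -0.21, below that of all 10000 random lists of similar signal, with krt5 at -0.63 and ppl at -0.62 lower but krt94 at 0.67 and atp6v1aa at 0.70 higher. Early zygotic patterning genes had a median of -0.11 (percentile 0.21), with eve1 at -0.87 and tbxta at -0.66 lower but her5 at 0.80 higher. Carbohydrate and energy metabolism lay at -0.12 (percentile 0.09), with tpi1b at -0.54 and, the other way, gys1 at 0.38. Cytoplasmic ribosomal proteins lay at -0.13 (percentile 0.12), with rplp0 at -0.36 and, the other way, rps14 at 0.33. Yolk, lipid transport and liver genes lay at -0.14 (percentile 0.01), and in the deposited ratio at percentile 2.67, inside the range of random lists. Maternal and germ plasm transcripts were on the high side at 0.13 (percentile 97.1, just inside the range), with btg4 at 1.59, org at 0.92 and bmp15 at 0.75. The glucocorticoid-responsive list as a whole had a median of 0.02 (percentile 56.4). Oxidative stress response genes lay at -0.09 (percentile 3.33), and stood apart in the deposited ratio at -0.17 (percentile 1.84). Mesoderm, somite and muscle genes lay at -0.03 (percentile 10.7), and stood apart with both channels over the median signal at -0.21 (percentile 0.265).

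Some genes were above the controls in 1 channel only at 5 hpf, 798 in vehicle and 965 in cortisol. Against the probe's own signal in the dim channel, or the lowest signal counted as measured there if that was larger, rabgap1l2 was at least 5.25-fold higher and il2rgb at least 3.50-fold lower in cortisol-treated embryos. Such bounds are open to dye bias, since no array had the dyes swapped.

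At 12 hpf, during segmentation, the comparison asked what differed 10 hours after the hormone was removed. The 4 members of the yolk, lipid transport and liver list with the largest ratios were lower, none of them 2-fold: apoa1b at -0.90, apoa2 at -0.82, apoa1a at -0.79 and apoa4b.1 at -0.76. The red signals of apoa1b and apoa2 were dim, 153.8 and 153.5. The gene apoea, which is not in that list, was higher by 3.06 with a dim green signal of 71.7. The insulin-like growth factor binding protein gene igfbp5a was higher by 4.84, but by 1.76 in the deposited ratio, and the lens crystallin gene cryba2a by 3.34 and 2.74. The proapoptotic gene baxa was lower at -1.36.

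At 12 hpf, 74 genes were at least 2-fold higher and 41 at least 2-fold lower. The deposited ratio gave 357 and 392, a share of higher genes of 47.7% in place of 64.3%. Among 6491 genes with both channels over the median signal, 60 were higher and 67 lower (47.2% higher) in the scanner signals, but 73 and 4 (94.8% higher) in the deposited ratio. Over all measured genes the deposited ratio kept 52 of the 74 higher genes at 2-fold and 0 of the 41 lower ones, although 40 of those 41 had the same sign. Of the 12 highest genes, 3 had both channels over the median signal and 3 had a green signal within 20 units of background, so most of these ratios rest on dim spots. Also among them were nr6a1b at 4.64 (2.62 in the deposited ratio), ippk at 4.36 (2.02 there), atf7a at 3.28 (2.101 there), plekha2 at 2.87, ppm1na at 2.47, bmerb1 at 1.68 and atp2b2 at 1.58. The local red background was raised over the array's median of 130 for ippk (203.8), plekha2 (184.3), nr6a1b (170) and ppm1na (164.5). It was also above it for atf7a (152.3), cryba2a (146.3) and apoea (140.3), but near it for igfbp5a (133.8), atp2b2 (133.2) and bmerb1 (125.7). Whether raised local background shaped these ratios was not tested. The mean of tnnt2c, 5.04 (0.87 in the deposited ratio), joined probes at 0.13 and 9.95, and that of arl8bb, 1.80, joined probes at 0.06 and 3.53, so neither gene has a settled value. The other genes among the 12 lowest at 12 hpf were zdhhc4 at -1.38, rpl7l1 at -1.36, cog2 at -1.32, dad1 at -1.28, cox10 at -1.25, atxn2l at -1.22, rfc2 at -1.22, ppp2r1bb at -1.21, ndufb10 at -1.18, tab3 at -1.18 and pdhb at -1.16. In the deposited ratio those 12 hpf values ranged from -0.77 for cog2 to -0.14 for dad1. Among list members, the secretory gene agr2 was higher by 1.06 and aifm1 lower at -0.88.

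At 12 hpf, 4 lists stood apart. The 19 measured yolk, lipid transport and liver genes had a median of -0.32 (percentile 0.01), and 5 of them were at least 1.5-fold lower. In the deposited ratio this median was -0.49. The 3 others were high: circadian clock genes at 0.14 (percentile 99.9), with nfil3-5 at 0.41, cytoplasmic ribosomal proteins at 0.25 (percentile 99.6, but 75.5 with both channels over the median signal), with rps14 at 0.80, and carbohydrate and energy metabolism at 0.06 (percentile 98.6), with eno1a at 0.66 but fbp1b at -0.69 and ldhba at -0.52. In the deposited ratio the medians of these 3 lists at 12 hpf were -0.03, -0.02 and 0.00, and each lay inside the range of random lists. Cell cycle and DNA replication genes had a median of -0.10 (percentile 38), with orc1 at -0.66, mcm6 at -0.66 and pcna at -0.54, and in the deposited ratio a median of -0.21 (percentile 0.36), which stood apart. Blood and erythroid genes lay at -0.18 (percentile 4.29), with lcp1 at -0.73 but spi1b at 0.37, and stood apart in the deposited ratio at -0.34 (percentile 2.32). Epidermis and ionocyte genes lay at -0.05 (percentile 24.4), and stood apart low in the deposited ratio (-0.18, percentile 2.33) and with both channels over the median signal (-0.18, percentile 1.82). Glucocorticoid-responsive genes lay at 0.03 (percentile 93.2).

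Signal in vehicle only was found for 7345 genes at 12 hpf and in cortisol only for 268, with the red channel dim. The integrin gene itga2b was at least 5.16-fold higher in cortisol-treated embryos, and rgl2 at least 1.97-fold. For no gene measured in vehicle only did the bound reach 2-fold.

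The comparison at 24 hpf asked which differences were present a day after fertilisation. Genes of early patterning were lower in cortisol-treated embryos: ved at -1.53, wnt8a at -1.11, pou5f3 at -1.0 and cdx4 at -0.93. The red signals of wnt8a and pou5f3 were dim, 137.5 and 150 over a background of 134. Of the mesoderm, somite and muscle list, myog at -1.25, msgn1 at -1.05 and myf5 at -1.04 were lower, although the list as a whole was not, and the deposited ratio of myog was only -0.33. The fibronectin gene fn1b lay at -1.69, the eye gene six7 at -1.60 with a dim red signal of 139.5, and the keratin gene krt99 at -1.96. Among higher genes were tbk1 at 1.32 and fancm at 1.37.

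At 24 hpf, 40 genes were at least 2-fold higher and 97 at least 2-fold lower. The deposited ratio gave 448 and 320, a share of higher genes of 58.3% in place of 29.2%. Among 6151 genes with both channels over the median signal, 51 were higher and 115 lower (30.7% higher) in the scanner signals, and 79 and 32 (71.2% higher) in the deposited ratio. Over all measured genes the deposited ratio kept 33 of the 40 higher genes at 2-fold, and 22 of the 97 lower ones. The other genes of the upper 12 were bmerb1 at 1.67, wbp2nl at 1.63, plppr5b at 1.61, ino80db at 1.41, fut9b.5 at 1.30, zdhhc5a at 1.29, atp2b2 at 1.28, pawr at 1.28, rgs5b at 1.22 and exorh at 1.22. Those of the lower 12 were lyar at -1.70, septin8a at -1.67, cnn3a at -1.56, rpl7l1 at -1.54, zdhhc4 at -1.5, morc2 at -1.48, fam76b at -1.37 and cog2 at -1.37. Of the 12 lowest genes at 24 hpf, 9 had both channels over the median signal, and six7, zdhhc4 and cog2 had not. The deposited ratio placed lyar at -0.40, rpl7l1 at -0.30 and fam76b at -0.07, all far from 2-fold, and six7 further out at -4.02. The matrix protease gene mmp2 lay at -1.02, but at -0.01 in the deposited ratio.

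At 24 hpf, 3 lists stood apart. The 31 measured early zygotic patterning genes had a median of -0.28 (percentile 0.01), 7 of them were at least 1.5-fold lower and none was 1.5-fold higher. Their median in the deposited ratio was -0.45. Oxidative stress response genes lay at -0.23 (percentile 1.24), with sqstm1 at -0.57 and cat at -0.56, and in the deposited ratio at -0.07, inside the random range. Circadian clock genes lay at 0.10 (percentile 97.7), with cry2 at 0.39 and per1b, the other way, at -0.84 (-0.06 in the deposited ratio). In the deposited ratio the clock median was 0.09 (percentile 82.0). Mesoderm, somite and muscle genes had a median of 0.06 (percentile 93.9) despite the low values of myog, msgn1 and myf5, and of 0.19 (percentile 99.5) in the deposited ratio. Glucocorticoid-responsive genes had a median of -0.05 (percentile 52.2) over 23 genes, but of -0.49 (percentile 0.22) over the 13 with both channels over the median signal, with per1b at -0.84, sgk1 at -0.57 and pck2 at -0.55. The deposited ratio placed that list at -0.06 (percentile 28.6). Carbohydrate and energy metabolism lay at 0.04 (percentile 95.3), and stood apart in the deposited ratio at 0.17 (percentile 98.7). Signal was found in vehicle only for 7247 genes at 24 hpf and in cortisol only for 318, and no bound reached 2-fold, the highest being mansc1, at least 1.67-fold lower.

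**Figure D2:**
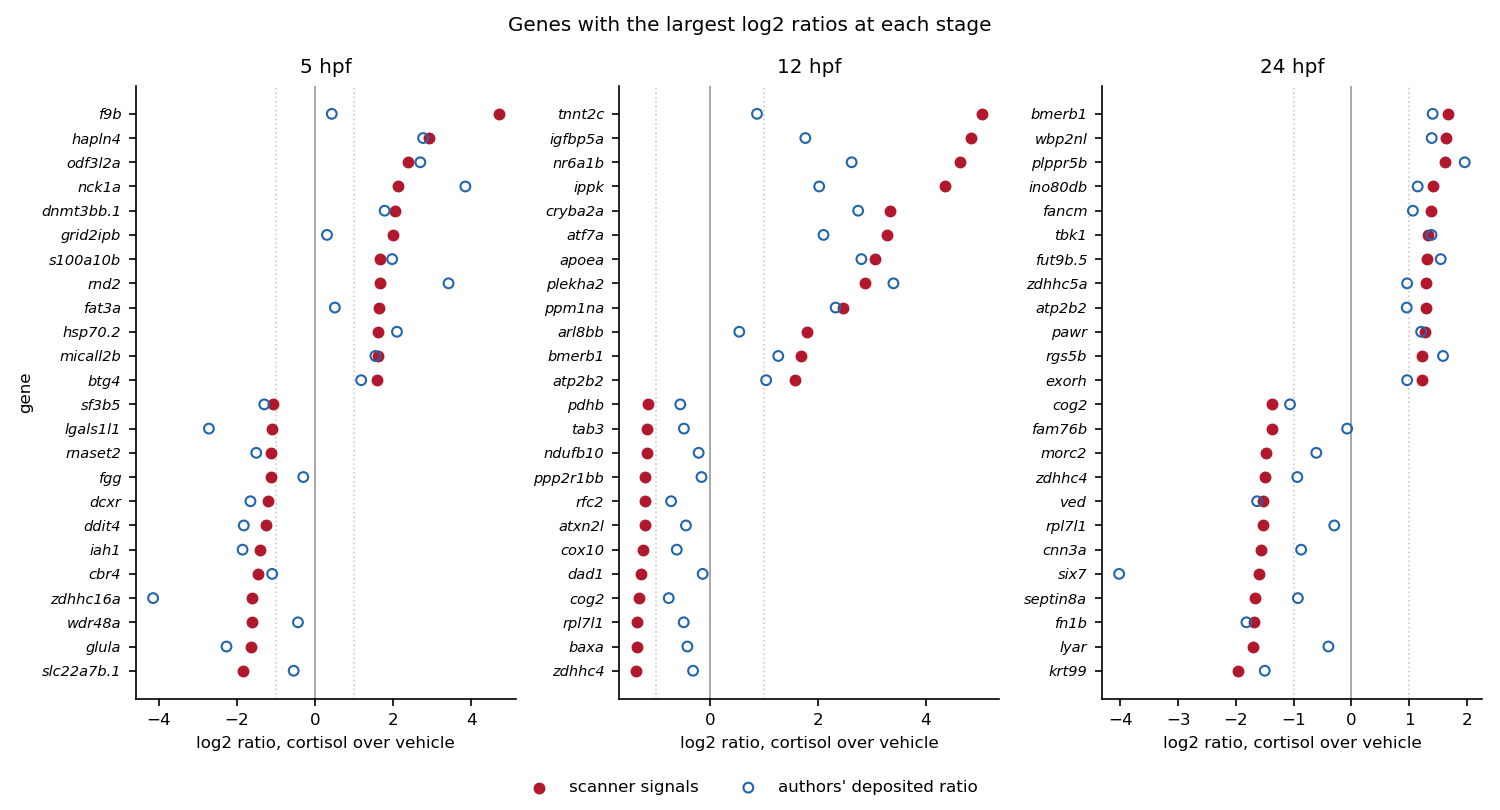
The 12 genes with the largest positive and the 12 with the largest negative log2 ratios (horizontal axis, cortisol over vehicle) at each stage, from the scanner signals (filled) and in the authors' deposited ratio (open). Dotted lines mark 2-fold. The deposited values of the lower genes at 12 hpf lie between -0.77 and -0.14.

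Across all 3 stages, 12 of 66 combinations of list and stage stood apart, where 3.3 would at the nominal 5%. Random lists were drawn gene by gene, whereas members of a list may vary together and lists share some genes, so 3.3 can be too low a benchmark. Of the 12 genes named in advance, mmp2 alone passed 2-fold, at 24 hpf (-1.02), with 0.02 at 5 hpf and -0.53 at 12 hpf, and its deposited ratios were -0.18, -0.25 and -0.01. The glucocorticoid receptor gene nr3c1 had log2 ratios of 0.20, 0.08 and -0.04 at 5, 12 and 24 hpf, against 0.27, -0.27 and -0.36 in the deposited ratio, and tsc22d3 of 0.34, -0.13 and -0.27. The immunophilin gene fkbp5 lay at 0.02 and 0.24 at 5 and 12 hpf, with 1.29 in the deposited ratio at 12 hpf, and was not measured in both channels at 24 hpf. The clock gene per1a lay at 0.18, 0.31 and -0.01, and per1b at -0.42, -0.30 and -0.84, with -0.72, -0.02 and -0.06 in the deposited ratio. The cortisol-inactivating enzyme gene hsd11b2 lay at 0.03 and -0.02 at 12 and 24 hpf, and at -0.65 and 0.06 in the deposited ratio. The protease gene mmp9 lay at 0.25, -0.25 and -0.15, and mmp13a and il1b, measured at 5 hpf only, at 0.58 and 0.07. The mineralocorticoid receptor gene nr3c2 and cxcl8a were not measured in both channels at any stage.

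**Figure D3:**
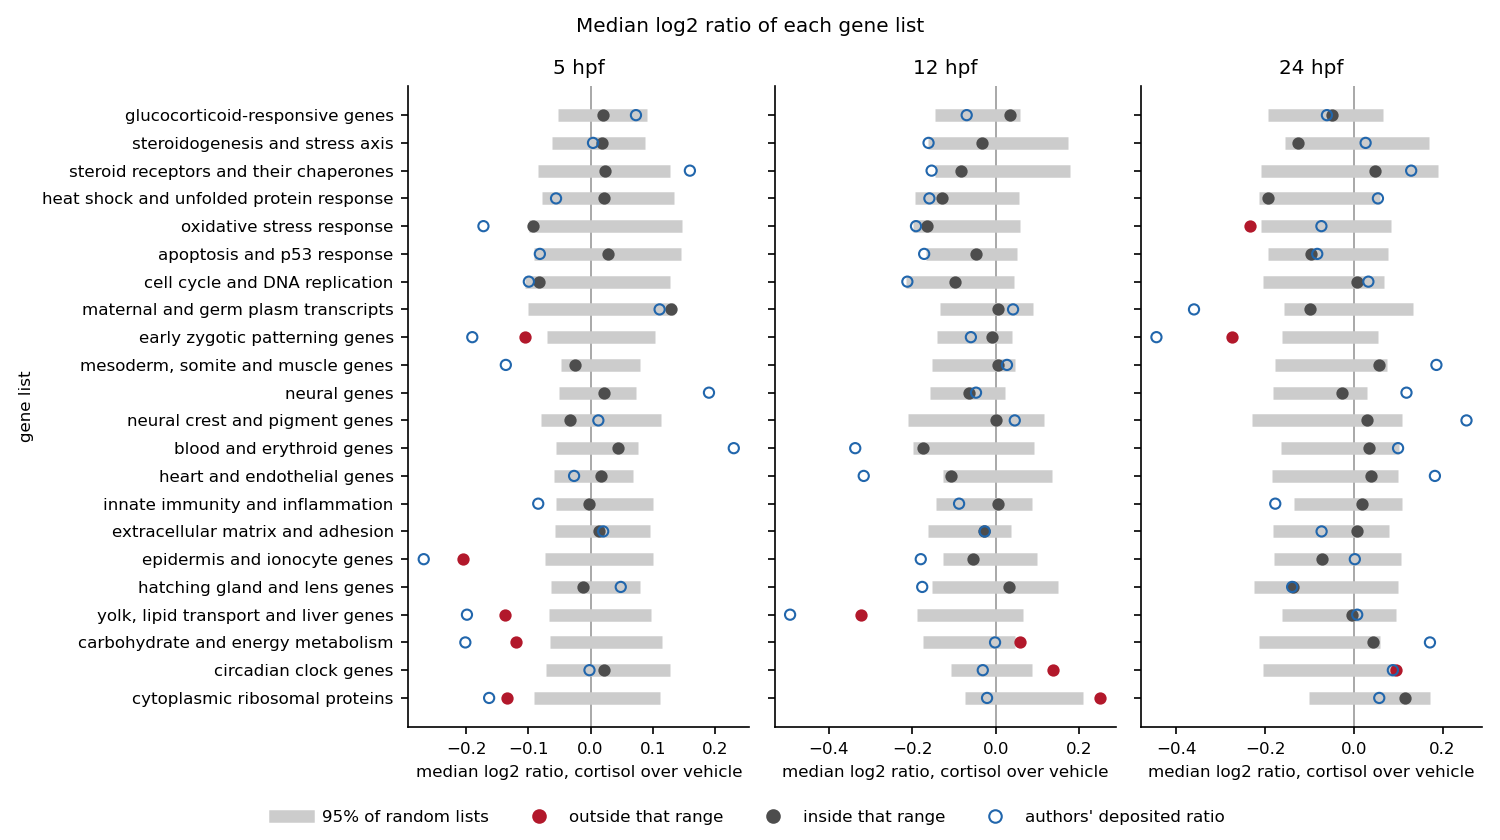
Median log2 ratio (horizontal axis, cortisol over vehicle) of 22 gene lists at each stage, with the range holding 95% of random lists of similar signal in grey and the authors' deposited ratio as open circles. Filled red circles lie outside the grey range, among them epidermis and ionocyte genes at 5 hpf (-0.21), yolk, lipid transport and liver genes at 12 hpf (-0.32) and early zygotic patterning genes at 24 hpf (-0.28).

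The stages were compared to ask whether the same genes differed throughout. No gene was at least 2-fold higher at all 3 stages, or lower at all 3, among 10381 genes measured at each. In the simulations many probes planted at 3-fold fell short of 2-fold, so shared changes could be missed. At 12 and 24 hpf, bmerb1 and atp2b2 were among the 12 highest genes at both stages, and zdhhc4, rpl7l1 and cog2 among the 12 lowest. In all, 23 genes were 2-fold higher at both, where independent lists would share 0.21, and 22 were lower at both, where 0.36 would be shared. The deposited ratio gave 92 shared higher genes (4.16 by independent lists) and 13 shared lower ones (5.82). This benchmark takes calls as spread evenly over signal levels, which they were not. In the scanner signals, 36 of the 74 higher genes at 12 hpf and 32 of the 40 at 24 hpf were among the 1277 and 1232 brightest. In the deposited ratio, 224 of 357 and 301 of 448 were among the dimmest. The benchmarks can therefore be too low, and how much sharing is due to signal level was not tested. Across genes, which are not independent replicates, Pearson's r between 12 and 24 hpf was 0.55 and Spearman's rho 0.50, while the deposited ratio gave 0.26 and 0.16. The correlation was 0.14 (rho 0.14) between 5 and 12 hpf and 0.08 (rho 0.06) between 5 and 24 hpf, with 0 shared genes in either direction. Independent lists would share 0.42 higher and 0.04 lower genes at 5 and 12 hpf, and 0.26 and 0.10 at 5 and 24 hpf. The lack of shared genes therefore does not show that these stages differed. In the deposited ratio the correlations of these pairs were 0.21 and 0.08. There, 46 genes were 2-fold higher at both 5 and 12 hpf, where 6.93 would be shared by independent lists, and 17 at both 5 and 24 hpf, where 8.02 would be. The genes lower at both numbered 4 and 8, where 3.75 and 3.14 would be shared. Per the array identifiers, the 24 hpf array shared a slide with an array of 12 hpf, and both had the same dyes and dim red signal, so a shared technical effect and a shared response to cortisol cannot be told apart in the correlation of these stages.

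Log2 ratios were also set against the change of the same genes between the vehicle channels of the 2 other stages, to ask whether cortisol moved genes along normal development. Pearson's r across genes was 0.08 (rho 0.10) for the 5 hpf ratio against the change from 12 to 24 hpf, 0.02 (rho 0.05) for the 12 hpf ratio against 5 to 24 hpf, and -0.11 (rho -0.08) for the 24 hpf ratio against 5 to 12 hpf. The stage change is itself confounded with the array.

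In the scanner signals the remaining lists lay inside the range of random lists at all 3 stages. Their medians at 5, 12 and 24 hpf were 0.02, -0.03 and -0.13 for steroidogenesis and stress axis genes, with cyp11a1.1 at -0.36, -0.27 and -0.48. They were 0.02, -0.08 and 0.05 for steroid receptors and their chaperones, and 0.02, -0.13 and -0.19 for heat shock and unfolded protein response genes, where hsp90b1 was lower at 12 hpf (-0.66). Apoptosis and p53 response genes lay at 0.03, -0.05 and -0.10, with baxa at -1.36 at 12 hpf and -1.17 at 24 hpf, and -0.06 in the deposited ratio at 24 hpf. Neural genes lay at 0.02, -0.07 and -0.03, neural crest and pigment genes at -0.03, 0.00 and 0.03, and heart and endothelial genes at 0.02, -0.11 and 0.04, with gata5 at -0.50, -0.37 and -0.72. Innate immunity and inflammation genes lay at 0.00, 0.01 and 0.02, extracellular matrix and adhesion genes at 0.01, -0.03 and 0.01, and hatching gland and lens genes at -0.01, 0.03 and -0.14. Neural crest and pigment genes stood apart at 24 hpf in the deposited ratio (0.25, percentile 98.6) and with both channels over the median signal (0.17, percentile 98.9). Neural genes stood apart at 24 hpf in the deposited ratio (0.12, percentile 97.53), as did maternal and germ plasm transcripts, at -0.36 (percentile 1.12), against -0.10 (percentile 11.5) in the scanner signals.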

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

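Both results here were picked by a rule fixed in advance, lists that stood apart in opposite directions at different stages, and no test of the difference between stages was possible. The median of cytoplasmic ribosomal proteins was -0.13 at 5 hpf and 0.25 at 12 hpf, a gap of 0.38 on the log2 scale. That of carbohydrate and energy metabolism genes was -0.12 and 0.06, a gap of 0.18. The low values at 5 hpf were present in the deposited ratio too (-0.16 and -0.20), whereas at 12 hpf its medians were -0.02 and 0.00, inside the range of random lists, so the opposition rests on the scanner signals alone. No gene was at least 2-fold higher at 1 stage and 2-fold lower at another in the scanner signals, against 14 between 5 and 12 hpf, 16 between 5 and 24 hpf and 12 between 12 and 24 hpf in the deposited ratio. No explanation of these results was tested.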

How the results depend on the processing

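The fit of the background on every spot, the leaving out of probes with disagreeing deposited values and 15 further pairings with stage changes (12 share an array with the ratio) were added after values had been seen; the other alternatives were planned. Counts of genes 2-fold higher and lower are given in that order, beside 110 and 27 at 5 hpf, 74 and 41 at 12 hpf, and 40 and 97 at 24 hpf; a count not given was within 1.5 times. The deposited ratio gave 589 and 380, 357 and 392, 448 and 320. The scanner software's processed signals gave 777 and 283, 561 and 300, 489 and 322. Normexp with offset 16 gave 209 and 48, 115 and 93, 63 and 222. Median centring in place of loess does not remove a trend of the ratio with signal. With it, all-gene medians moved to 0.16, -1.70 and -1.21, with counts of 428 and 10, 21 and 9127, 0 and 7329. Relative to those medians the counts were 216 and 15, 2661 and 1949, 1508 and 1224. No background correction gave 113 and 19 at 12 hpf and 50 lower at 24 hpf. No filter on dim probes gave 25 and 62 at 24 hpf. Both channels over the median gave 56 higher at 5 hpf and 67 lower at 12 hpf. The brightest probe gave 115 and 103 at 12 hpf and 178 lower at 24 hpf. A 1.5-fold threshold gave 568 and 180, 202 and 414, 155 and 546, and a 3-fold threshold 25 and 5, 26 and 0, 3 and 6. Normexp on every spot gave 41 higher at 5 hpf and 242 and 26 at 12 hpf. Probes with disagreeing deposited values left out gave 71 and 13 at 5 hpf and 38 higher at 12 hpf. The correlation of 12 with 24 hpf (0.55) was 0.26 in the deposited ratio, 0.25 in the processed signals, 0.78 with median centring, 0.41 with no filter on dim probes and 0.35 with normexp on every spot. That of 5 with 24 hpf (0.08) was 0.18 with both channels over the median and -0.27 with median centring, which turned that of 5 with 12 hpf to -0.28. Median centring also moved the correlations with the vehicle stage change to -0.20, -0.32 and -0.56 for 5, 12 and 24 hpf; the 15 added pairings lay between -0.11 and 0.32. Lists standing apart (5, 4 and 3) numbered 9, 0 and 5 with median centring, 8 at 5 hpf with unmatched random lists, 2 at 12 hpf with no filter and with both channels over the median, 5 at 24 hpf with processed signals, 1 with the brightest probe and 6 in the deposited ratio. Epidermis and ionocyte, early zygotic and ribosomal lists at 5 hpf stood apart on the low side in 10 of 10 alternatives by their percentile, carbohydrate metabolism at 5 hpf, yolk genes at 12 hpf and early zygotic genes at 24 hpf in 9 of 10, and yolk genes at 5 hpf in 7 of 10. On their own side, ribosomal proteins at 12 hpf stood apart in 5 of 10, clock genes at 12 and at 24 hpf and carbohydrate metabolism at 12 hpf in 3 of 10 each, and oxidative stress genes at 24 hpf in 2 of 10. With median centring, which moved the all-gene median too, those medians at 5 hpf were 0.16 for epidermis, 0.17 for early zygotic, 0.42 for ribosomal and 0.078 for carbohydrate genes, and the epidermis median was -0.10 both with the brightest probe and with no filter on dim probes. Carbohydrate metabolism at 12 hpf turned to -2.14 with median centring, -0.0031 with no filter, -0.071 with both channels over the median and -0.0022 in the deposited ratio. Its median also lay just below 0 with no background correction and, at -0.016, with normexp on every spot, although it stood apart on the high side of matched lists there. Clock genes at 12 hpf turned to -1.10 with median centring, -0.0053 with both channels over the median and -0.032 in the deposited ratio, and at 24 hpf to -1.28 with median centring. Ribosomal proteins at 12 hpf lay at 0.068 with offset 16, 0.88 with no background correction and 2.12 with normexp on every spot, and turned to -3.03 with median centring, -0.018 in the processed signals and -0.021 in the deposited ratio. Of the named genes past 2-fold (28, 25 and 31 at the 3 stages), the numbers still 2-fold were 28, 13 and 18 with the processed signals, and in the same order for the others: in the deposited ratio (21, 10 and 18), with no filter on dim probes (23, 17 and 13), with normexp on every spot (22, 11 and 31), with no background correction (26, 23 and 24) and with median centring (20, 21 and 19). Those that changed sign did so with median centring alone: atp2b2 (-1.56) and bmerb1 (-1.39) at 12 hpf, and at 24 hpf atp2b2 (-1.15), bmerb1 (-0.73), exorh (-1.35), fancm (-1.03), fut9b.5 (-0.81), ino80db (-1.18), pawr (-1.29), plppr5b (-0.27), rgs5b (-0.60), tbk1 (-1.14), wbp2nl (-0.88) and zdhhc5a (-1.15); relative to the all-gene median 0 at 12 hpf and 2 at 24 hpf did. The 12 top genes per direction were chosen to have 1 sign in all probes and in the deposited ratio, so their stable sign there was built in. Of all 97 genes 2-fold lower at 24 hpf, 91 kept their sign in the deposited ratio and in the processed signals. With the brightest probe, 71 of the 74 higher genes at 12 hpf did. Named genes under 2-fold could change sign in the deposited ratio, as nr3c1 (0.08 against -0.27) and hsd11b2 (0.03 against -0.65) did at 12 hpf. At 12 hpf, 224 of 357 higher genes in the deposited ratio were among the 1277 dimmest, against 3 of 74 in scanner signals. At 24 hpf these were 301 of 448 and 0 of 40 among the 1234 dimmest. Deposited lower genes there numbered 39 of 392 and 41 of 320. At 5 hpf, 67 of 589 deposited higher genes were among the 1931 dimmest. Most deposited higher genes at 12 and 24 hpf were thus dim. Among these dimmest genes the log2 ratio from the scanner signals had an SD of 0.16 at both stages, against 0.96 and 0.99 in the deposited ratio. Few scanner ratios of dim genes could therefore reach 2-fold, so the contrast reflects both ratios. Apart from median centring, the cause of these and the earlier moves was not tested. Red signal over background (330 and 290 at the 95th percentile) limits the 12 and 24 hpf ratios. A slide block, leaving out replicates and dye-swapped arrays were not run. The deposited values at 5 and 12 hpf are read as means, 24 hpf is a single experiment, and no dye was swapped. No paired analysis was possible because each stage has 1 set of values and no test.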

Other observations

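Of the tests here, those on dye effects and on developmental stage were chosen after the list results were seen. Those on dim spots were set down before their outcome was known. Synthetic spike-in RNAs gave median log2 ratios of 0.76, 0.92 and -0.78 at 5, 12 and 24 hpf over 10 probes, correlated between stages at 0.976 to 0.984. The probes ranged from -1.93 to 3.23 at 5 hpf, from -1.28 to 3.28 at 12 hpf and from -2.54 to 1.98 at 24 hpf. The intended ratios of the spike-ins were not used here. The medians thus measure no dye bias, and the correlations measure no agreement of the embryo ratios between stages. At 24 hpf the late-stage markers of the label check, looked at here only afterwards, had a median log2 ratio of 0.10 (percentile 96.7, inside the range of random lists) and of 0.24 (percentile 99.2) in the deposited ratio. The early-stage markers lay at -0.54 and -0.86, below all random lists, but 15 of their 19 symbols are in the early zygotic patterning list.

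Early zygotic patterning genes were lower at 24 hpf, with ved at -1.53, while wnt8a and pou5f3 rest on dim red spots. Noise of dim spots is argued against, since with both channels over the median signal the list still lay at percentile 1.12, with a median of -0.27 over 18 genes. This filter did not lower the spread between probes of a gene (pooled SD 0.38 against 0.33), so noise of brighter spots stays open. The list's median was -0.13 in the weakest of 10 alternatives. A dye effect of the list's probes stays open. The 31 members measured in the same dyes at 12 hpf were lower at 24 hpf by a median difference of -0.27 (95% bootstrap interval -0.42 to -0.11). That interval resamples genes and measures no variation between arrays or embryos. The list was also picked for its low value at 24 hpf, so a difference in this direction was partly built in. At 5 hpf the list stood apart low in these dyes too (-0.11, percentile 0.21). A candidate explanation that stays open is that the cortisol-treated embryos were further in development: over the 12286 genes outside the list, the 24 hpf ratio correlated with the vehicle change from 12 to 24 hpf at a rho of 0.16, although the shared channel pulls it down. Against the vehicle change from 5 to 24 hpf, with the same shared channel, rho over all measured genes was only 0.0074. Against the vehicle change from 5 to 12 hpf the planned rho was -0.08. An uncorrected trend with signal, or 1 batch of embryos at a different pace, is not excluded in a single experiment.

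Yolk, lipid transport and liver genes were lower at 12 hpf, apoa1a and apoa4b.1 among them, while apoa1b and apoa2 rest on dim red spots. Noise of dim spots is argued against by percentile 0.23 with both channels over the median signal, a median of -0.42 over 11 genes, which leaves out apoa1b and apoa2. Noise of brighter spots stays open, since this filter did not lower the spread between probes of a gene (pooled SD 0.37 against 0.33). A dye effect of the probes stays open. The median difference between 12 and 24 hpf was -0.28 over 19 genes (interval -0.60 to -0.10), but the interval resamples genes and not arrays. The list was also picked for its low value at 12 hpf, so a difference in this direction was partly built in. At 5 hpf the list stood apart low in these dyes too (-0.14, percentile 0.01). A different amount of yolk or yolk syncytial layer tissue in the embryos, an effect of cortisol, and 1 deviating array among the averaged ones may each account for it, and none of these was tested.

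Epidermis and ionocyte genes were lower at 5 hpf, krt5 and ppl among them. Noise of dim spots is argued against by percentile 0.25 with both channels over the median signal, a median of -0.21 over 17 genes. This filter hardly lowered the spread between probes of a gene (pooled SD 0.19 against 0.21). The 1931 dimmest genes already had the smaller spread of ratios (SD 0.076, against 0.33 in the 1931 brightest). Noise of brighter spots therefore stays open, and the list was picked for its low value at 5 hpf. A dye effect of the list's probes stays open: the 22 members measured at 5 and 12 hpf had a median difference of 0.0059, and its interval, -0.16 to 0.14, holds both 0 and the gap between the list's medians of -0.21 and -0.05 at these stages. That cortisol-treated embryos were behind in development cannot be told from these arrays: rho with the vehicle change from 5 to 12 hpf was 0.20 over 19283 genes and with the cortisol-channel change -0.06, each in the direction that the shared channel gives by itself.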
